A study of Mus musculus and Rattus norvegicus with 2 samples.

How the data were processed

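RNA was measured by sequencing in 2 libraries of placental labyrinth, the zone of the rodent placenta where maternal and fetal blood exchange substances. The mouse library came from C57BL/6J mice, an inbred strain, at gestational day 17.5, and the rat library came from SD rats at gestational day 20.5. Per the labels' protocols, equal amounts of RNA from 3 to 4 litters were pooled into each library, poly(A) RNA was selected and a directional kit was used. Each species therefore had 1 library. Differences between litters were averaged within a pool and cannot be estimated, and species, gestational day and strain differ together.

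The authors deposited a single table of estimated counts per gene symbol, with a column for each library. Per the submitters' processing notes, Trimmomatic 0.3.9 and Salmon 1.9.0 were used. The builds GRCh38.p14 and GRCm39 are named there for both libraries, and the rat reference is not given in the sources used here. Salmon assigns reads to transcripts and gives estimates that need not be whole: 56.3% of the nonzero mouse values and 70.4% of the nonzero rat values were not whole numbers. How transcripts were combined into symbols is not given in the sources used here. The kit keeps strand, and whether counting used it is not given in the sources used here, so overlapping and antisense genes are uncertain, as are families of near-identical copies. The values were not divided by transcript length, so a ratio between species also carries any difference in transcript length. The table holds 3 other columns of per-sample values, which belong to no sample of this study and were not used. Of the rows, 1 names no gene; it held 41 rat counts, 0.000398% of the rat total, and was left out. Mitochondrially encoded genes were not analysed here, since none of the 13 fixed for that list had a value.

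Symbols are in capitals in the deposited table. They are written here in mouse spelling where the mouse reference holds them, which was the case for 19334 of 25249 symbols. The table gives no coordinates and the mouse reference at hand (GRCm38) is another build than the one the notes name, so no coordinates are printed.

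Counts were divided by the total over all symbols listed for that species and expressed as CPM, the usual scaling of a count to its library total. Ratios were taken over symbols with a value for both species and at least 10 counts in either library. The log2 ratio of rat to mouse was computed after adding 0.5 count to each value; folds are ratios of CPM without that addition and are given only where both libraries had at least 10 counts. The 95% interval of a ratio is an exact Clopper-Pearson binomial interval on the estimated counts, rounded to whole numbers first. It covers counting error only, since reads carry no molecular identifiers and animals are not replicated. Over the 2627 genes with at least 500 counts in both libraries, no interval bound lay farther than 13.2% from its ratio. A gene listed at 0 has a one-sided 95% upper limit of 3 counts, which is 0.257 CPM in mouse and 0.291 CPM in rat. No fold is given against such a value, because genes used by every cell are also listed at 0.

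With 1 library per species no test across genes was possible and no p-value is given. Genes are described by a rule of size: a ratio of at least 4-fold, with 0.5 count added, and a counting interval that excludes equality, so genes at 0 in a library are counted. Before the data were examined, 27 gene lists were fixed. For each list with at least 4 measured members, the median log2 ratio was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list is said to stand apart below the 2.5 or above the 97.5 percentile, as a description of these libraries. The genes named were also chosen by a fixed rule. They are the organic cation transporters, the extreme members in each direction and the most abundant member of each list (up to 4 a list), and the 10 genes with the largest ratio in each direction among those with at least 50 CPM in one library and 10 counts in the other. The 5 most abundant genes in each direction with under 10 counts in the other library complete the rule. Other genes named were chosen after their values were seen, and the text marks them.

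Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. edgeR 4.0.16 and DESeq2 1.42.0 under R 4.3.3 were used only for alternative scaling factors on the rounded counts. The procedure was tested on simulated counts for 11876 genes with the real levels and totals, 200 of them changed. It recovered 47 of 50 genes changed 4.5-fold and all 50 genes each of those changed 8-fold, 16-fold and 32-fold, and called 1 of 11676 unchanged genes. Of 100 unchanged lists of 15 genes, 2 stood apart. The simulation held counting error alone, with genes drawn independently and no variation between animals. These rates are therefore not error rates of the real ratios and lists. Alternatives varied the scaling, the filter on low counts, the pseudocount, the threshold, the summary and matching of lists, the removal of lineage-specific families, and thinning to the smaller total. Division by each species' own transcript length was planned and not run, since rat transcript lengths were not at hand. Restriction to genes with 1 mouse RefSeq mRNA (curated and predicted records counted together) was added after the data had been seen.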

Results

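Poly(A) RNA was sequenced from the placental labyrinth of mice at gestational day 17.5 and of rats at gestational day 20.5, with 1 pooled library per species. The mouse library held 11659770 estimated counts over 20969 symbols and the rat library 10306470 over 18532 symbols. The 10 most abundant genes took 14.5% of the mouse counts and 14.8% of the rat counts. Both species had a value for 16836 symbols, of which 12380 reached 10 counts in either library and were compared. No value has a replicate error, because each species had a single library. The question, from the title of the series, was whether the exporter MATE1 is a placental transporter of the rat and not of the mouse, with metformin and MPP+ as the substances that reach the fetus.

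Slc47a1, which encodes MATE1, an exporter of organic cations, was listed at 1183 counts in the rat labyrinth and at 0 in the mouse labyrinth. The rat value was 114.8 CPM with a 95% counting interval of 108 to 122 CPM. For a count of 0 the one-sided 95% limit is 3 counts, which is 0.257 CPM in the mouse library, for counting error alone. Among the organic cation transporters of the rat library, only Slc6a2, the noradrenaline transporter, had a higher value, at 193 CPM, and Slc22a3, which encodes the uptake transporter OCT3, came next at 98.5 CPM. The related exporter Slc47a2 (MATE2) was listed at 2.66 counts in rat and 0 in mouse, below the level where a difference could be detected. Rps27, a ribosomal protein gene that every cell uses, is also listed at 0 in the mouse library, as Rps14 is in the rat library, so the mouse value of Slc47a1 is given as listed and no fold is drawn from it.

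Several other members were close to equal between the species. Slc22a3 stood at 105 CPM in mouse and 98.5 CPM in rat, a ratio of 1.07 toward mouse with a counting interval of 0.979 to 1.16, which includes equality. Slc6a2 was 1.07-fold higher in rat (interval 1.01 to 1.14). Slc22a4, a carnitine and ergothioneine transporter, stood at 34.4 CPM in mouse and 38.3 CPM in rat. Slc6a4, the serotonin transporter, stood at 3.52 and 3.46 CPM, and the vesicular monoamine transporter Slc18a2 at 28.6 and 28.2 CPM.

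Other members differed. Slc22a5, the carnitine transporter OCTN2, was 6.80-fold higher in mouse (interval 5.85 to 7.96), the thiamine transporter Slc19a2 was 4.69-fold higher in mouse (3.88 to 5.72), and Slc18a1 was 9.48-fold higher in mouse at a low level (4.93 to 18.9). The choline transporter Slc44a1 was 4.54-fold higher in rat (3.44 to 6.09). Slc22a1 (OCT1), Slc29a4 (PMAT) and Slc19a3 were listed at 1.03, 3.26 and 1.56 CPM in mouse and at 0 in rat. No difference beyond counting error was seen for Slc22a2 (OCT2), at 1.201 CPM in mouse and 0.679 CPM in rat. The counting interval of its rat to mouse ratio, 0.193 to 1.498, includes equality. Slc6a3 was at 0 in both libraries and shows no difference either. Of the 14 measured members, 2 were at least 4-fold higher in rat, 6 were at least 4-fold higher in mouse and 6 were within 4-fold. These counts use the ratio with 0.5 count added and so include Slc47a1, Slc22a1, Slc29a4 and Slc19a3, each at 0 in a library; for Slc22a1 the counting interval begins at 2.46-fold. The list's median log2 ratio of -0.43 lay at the 30.7 percentile of matched random lists.

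**Figure D1:**
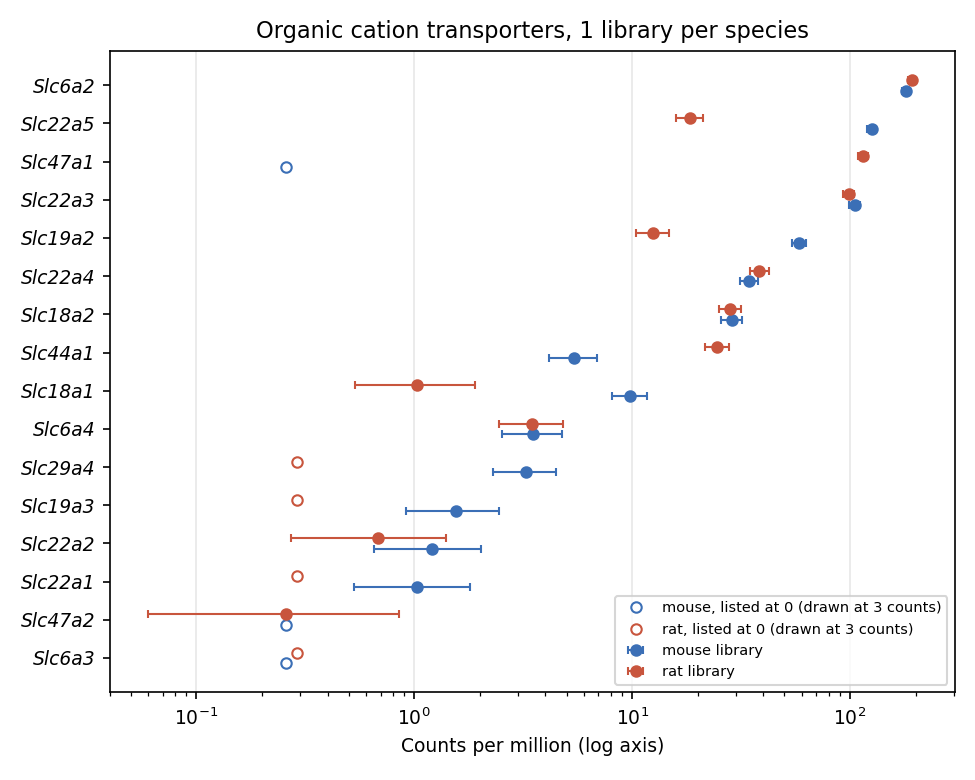
CPM of the organic cation transporters (log axis) in the mouse library and the rat library, with 95% binomial counting intervals; open symbols mark genes listed at 0, drawn at 3 counts. Slc47a1 stands at 114.8 CPM in rat and is listed at 0 in mouse, while Slc22a3 and Slc6a2 nearly coincide.

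Over all 12380 genes compared, 1864 were at least 4-fold higher in rat and 2637 at least 4-fold higher in mouse, and 5275 (42.6%) lay within 2-fold. Genes under 10 counts in the lower library made up 1002 of the first group and 1719 of the second. Among the 9406 genes with at least 10 counts in both libraries, 862 were at least 4-fold higher in rat and 918 in mouse, and 55.5% lay within 2-fold. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.439 and Spearman's rho was 0.627. With at least 10 counts in both libraries these were 0.698 and 0.691.

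Toward rat, the largest ratio belonged to Ifnk, which encodes an epithelial interferon and stood at 3.34 CPM in mouse and 2513 CPM in rat, a 751-fold difference (counting interval 549 to 1057). The prolactin family hormones Prl8a2 and Prl4a1 were 448-fold (299 to 708) and 140-fold (126 to 155) higher in rat, while more of the measured prolactin family was at least 4-fold higher in mouse (7 of 15) than in rat (3). The lysosomal protease Ctsl was 333-fold higher in rat, at 3350 CPM, and its near relatives in the placental cathepsin cluster make the assignment of its reads uncertain. Akr1c14, a hydroxysteroid dehydrogenase, was 232-fold higher in rat, and Ttr, the carrier of thyroxine, 152-fold. The sorting receptor Sort1 was 155-fold, Abhd2 119-fold, the protease inhibitor Cst6 100-fold and the membrane protease St14 84.9-fold higher in rat.

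Toward mouse, the largest ratio belonged to Acer2, an alkaline ceramidase, at 197 CPM in mouse and 1.18 CPM in rat, a 168-fold difference (counting interval 96.8 to 328). Ech1 and Nadk, metabolic enzymes, stood at 150 and 165 CPM in mouse against 1.08 and 1.89 CPM in rat. Numa1 of the mitotic spindle (181 against 1.65 CPM), the endocytic adaptor Picalm (205 against 2.55 CPM), the adhesion protein gene Sorbs3 (279 against 2.49 CPM) and the ribosomal protein gene Rps20 (481 against 5.62 CPM) had ratios of the same order. Inhbb, an inhibin and activin subunit, stood at 263 and 2.61 CPM, and Fmr1nb at 146 and 1.16 CPM. Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 1989 and 18.6 CPM. Rps20, like Rps14 and Rps27, is a ribosomal protein gene that every cell uses, and its low rat value is given as listed. What lowers it was not tested. At least 10 counts in both libraries therefore do not show that a large ratio is a species difference in expression. The counting intervals do not cover this uncertainty.

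In total 293 genes had at least 50 CPM in one library and under 10 counts in the other. The most abundant toward mouse were the leptin receptor Lepr (2485 CPM, listed at 0 in rat), Sct (secretin, 1214 CPM), the adhesion and Wnt signalling gene Ctnnb1 (715 CPM), Rps14 (594 CPM, listed at 0 in rat) and the kinase gene Limk2 (503 CPM). Toward rat they were the aminopeptidase Anpep (572 CPM), Tulp4 (330 CPM), the ribosomal protein gene Rps27 (271 CPM), Entpd4 (179 CPM) and the GABA receptor subunit Gabbr1 (172 CPM), all listed at 0 in mouse. Rps14, Rps27 and Ctnnb1 are used by every cell. Among genes with 1 curated mouse RefSeq mRNA and at least 500 counts in the other library, the share under 10 counts was 0.833% in mouse and 2.13% in rat where the reference held no predicted mRNA, and 13.6% and 22.5% where it held 4 or more.

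**Figure D2:**
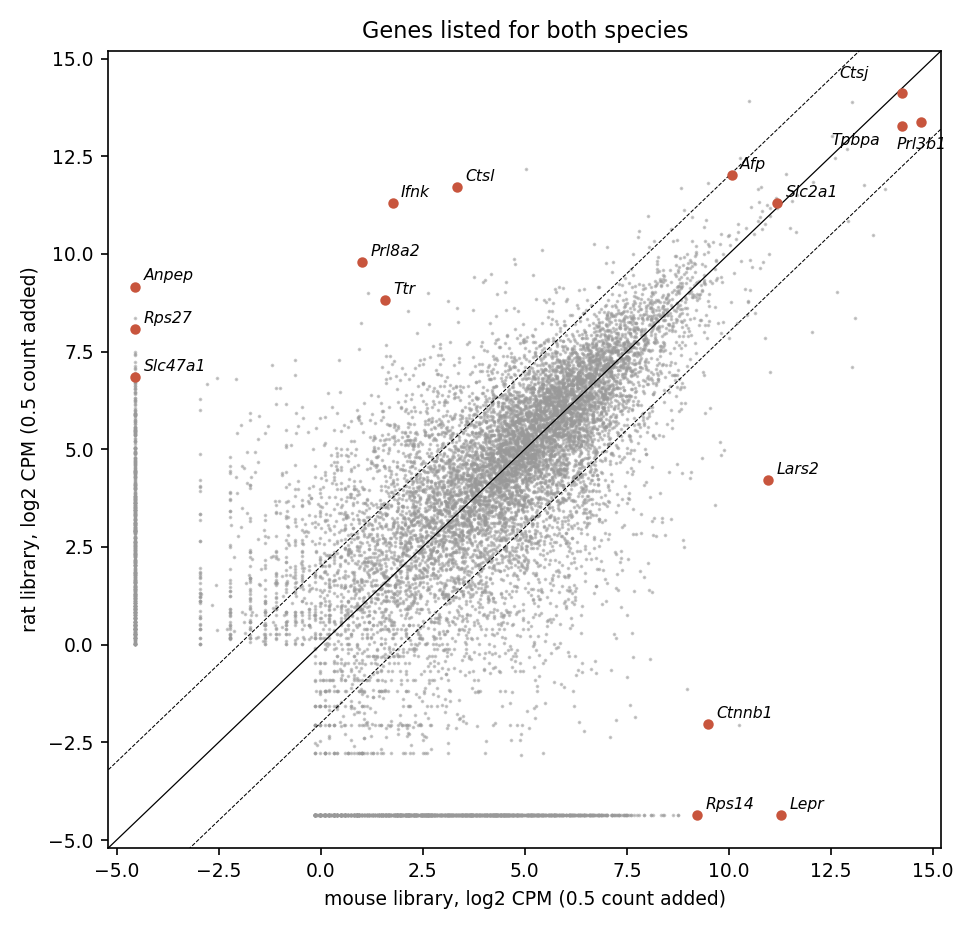
Rat against mouse log2 CPM, with 0.5 count added, for the 12380 genes compared; the solid line marks equality, the dashed lines a 4-fold difference, and red points are named genes. The rows of points at the left and lower edges are the genes listed at 0 in mouse (676) or in rat (1309), among them Slc47a1 and Rps14.

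**Figure D3:**
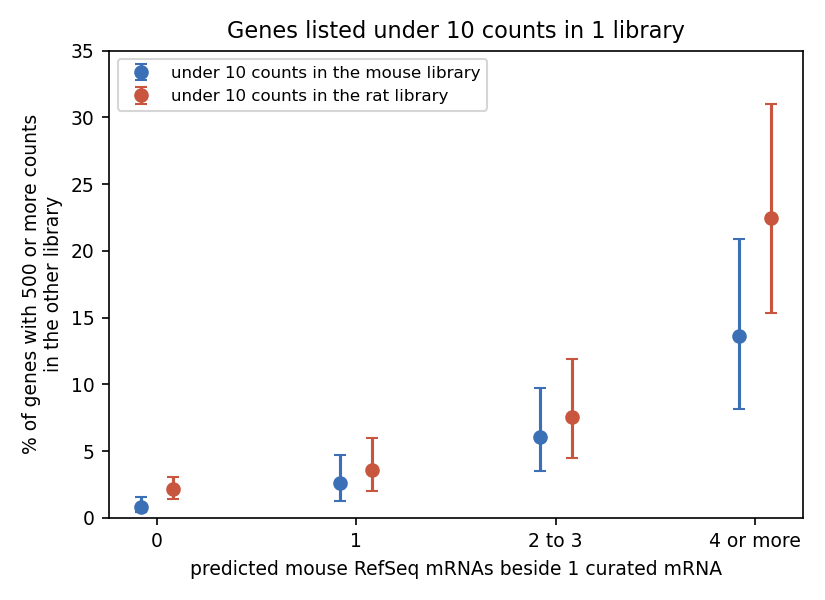
Share of genes under 10 counts in the mouse or the rat library, in percent of genes with at least 500 counts in the other library, by the number of predicted mouse RefSeq mRNAs beside 1 curated mRNA; bars are 95% exact binomial intervals. The share in mouse goes from 0.833% with no predicted mRNA to 13.6% with 4 or more, and in rat from 2.13% to 22.5%.

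Among the other drug transporters, 7 of 9 measured organic anion and bile acid transporters were at least 4-fold higher in rat and 1 in mouse. Its median log2 ratio was 3.64, the 99.5 percentile of matched random lists. Slco4c1 was listed at 24.8 CPM in rat and 0 in mouse, and 6 of the 9 members were under 10 counts in a library, so that the median depends on the pseudocount and was 2.08 with 5 in place of 0.5. Slco2a1, the prostaglandin transporter, went the other way and was 23.6-fold higher in mouse (21.0 to 26.7). Slco4a1, named after its values were seen, was 7.43-fold higher in rat. Without the filter on low counts this list no longer stood apart, at the 57.1 percentile. With at least 10 counts in both libraries fewer than 4 members remained, so no value was obtained. Yolk sac endoderm markers were higher in the same library, with a median log2 ratio of 2.64.

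The ABC efflux transporters did not move together: 2 of 13 were at least 4-fold higher in rat, 4 in mouse, and the median log2 ratio was 0.22 at the 67.2 percentile. Abcg1, a cholesterol exporter, was the most abundant, 2.79-fold higher in rat. Abcc2 was listed at 4.85 CPM in rat and 0 in mouse, and Abcc1 at 9.49 CPM in mouse and 0 in rat. Of the efflux pumps of the placental barrier, named after their values were seen, Abcg2 (BCRP) was 9.58-fold higher in mouse (6.49 to 14.4), and the P-glycoprotein genes went apart: Abcb1a was 1.16-fold higher in rat (1.02 to 1.31) and Abcb1b 1.67-fold higher in mouse (1.46 to 1.9).

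Nutrient transporters showed opposite directions within each class. The glucose transporter Slc2a1 was abundant in both labyrinths, at 2330 CPM in mouse and 2532 CPM in rat. Slc2a12 was listed at 47.3 CPM in rat and 0 in mouse, and Slc16a2 at 2.49 CPM in mouse and 0.194 CPM in rat. Named after their values were seen, Slc2a3 (GLUT3) and the lactate transporter Slc16a3 were 9.49-fold and 9.52-fold higher in rat, and Slc16a1, its counterpart on the other syncytial layer of the mouse labyrinth, was 7.49-fold higher in mouse. Of the 13 measured glucose and monocarboxylate transporters, 3 were at least 4-fold higher in rat and 3 in mouse, with a median log2 ratio of 0.18 at the 59.8 percentile.

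Amino acid transporters were more often higher in mouse, with 9 of 23 at least 4-fold higher there and 5 in rat. The median log2 ratio of -0.94 lay at the 1.80 percentile. Slc7a5 (LAT1), the most abundant member, was 4.64-fold higher in rat (4.503 to 4.78). Named after their values were seen, its partner Slc3a2 (2.67-fold) and Slc38a2 (10.4-fold) were also higher in rat, while the arginine transporter Slc7a1 was 24.9-fold higher in mouse. Slc6a9 stood at 44.6 CPM in rat and 0.515 CPM in mouse, and the taurine transporter Slc6a6 was listed at 172 CPM in mouse and 0 in rat. The list no longer stood apart under several alternatives, at the 3.03 to 9.23 percentiles, among them 7.45 with at least 10 counts required in both libraries. Junctional zone (median -1.29) and sinusoidal giant cell markers (-1.66) lay toward mouse as well, and yolk sac endoderm markers (2.64) toward rat. Of 5 nucleoside transporters, Slc28a2 was 7.72-fold higher in rat, Slc29a1 (ENT1) 3.91-fold higher in mouse, and Slc29a2 was listed at 4.18 CPM in mouse and 0 in rat; 1 was at least 4-fold higher in rat and 2 in mouse, with a median log2 ratio of -1.964 at the 10.8 percentile.

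Vitamin and metal transport genes went both ways. The transferrin receptor Tfrc, the most abundant member, was 4.48-fold higher in rat (4.40 to 4.57). Named after their values were seen, the iron transporters Slc11a2 (DMT1) and Slc40a1 (ferroportin) were 40.2-fold (34.7 to 46.8) and 6.92-fold (6.55 to 7.32) higher in rat, the zinc and iron importer Slc39a8 was listed at 1.69 CPM in mouse and 0 in rat, and the vitamin transporter Slc5a6 was 14.6-fold higher in mouse (12.1 to 17.5). The zinc and iron importer Slc39a14 was listed at 13.4 CPM in rat and 0 in mouse, and the calcium pump Atp2b4 at 34.7 CPM in mouse and 0 in rat. Over the 23 measured vitamin, iron, zinc and calcium genes, 6 were at least 4-fold higher in rat and 4 in mouse, with a median log2 ratio of 0.30 at the 74.1 percentile. Among 16 lipid uptake genes, 2 were at least 4-fold higher in rat and 4 in mouse, with a median of 0.12 at the 52.3 percentile; the 6 with 1 mouse mRNA record had a median of -1.28 at the 1.21 percentile, toward mouse. Slc27a2 was 11.2-fold higher in rat, Fabp3 2.08-fold higher in mouse, and Slc27a6 was listed at 38.9 CPM in mouse and 0 in rat.

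Markers of the trophoblast layers separated the libraries. Syncytiotrophoblast markers were higher in rat, with 5 of 16 at least 4-fold higher there, 2 in mouse, and a median log2 ratio of 1.465 at the 99.97 percentile. Yolk sac endoderm markers were higher in rat too, with a median of 2.64, and members such as Tfrc, Slc2a1 and Vegfa are also used by other cells. Tfrc was the most abundant, Synb (syncytin B) was listed at 59.8 CPM in rat and 0 in mouse, and Slc16a1 was the member farthest toward mouse. Synb has 6 mouse mRNA records. Its 0 is given as listed, as for Slc47a1, and does not show that the RNA is absent in mouse. The transcription factor Gcm1 (3.10-fold) and Vegfa (2.47-fold), named after their values were seen, were higher in rat, and Ly6e was 4.93-fold higher in mouse. With only the 4 members that have 1 mouse mRNA record, the list lay at the 66.7 percentile.

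Markers of sinusoidal giant cells, the trophoblast cells that line maternal blood spaces, lay toward mouse, with 4 of 9 at least 4-fold higher there and 1 in rat. Their median log2 ratio was -1.66 at the 0.20 percentile. Prl3b1 (placental lactogen II) stood at 26819 CPM in mouse and 10726 CPM in rat (interval of the ratio 2.48 to 2.52 toward mouse), Lepr was listed at 0 in rat, and the cathepsin Ctsr was 10.7-fold higher in rat. Against random lists not matched on expression the list lay at the 4.32 percentile and did not stand apart. Prolactin family hormones had a median of -1.63 at the 0.010 percentile, with 7 of 15 at least 4-fold higher in mouse and 3 in rat. Prl3d1 (placental lactogen I) was listed at 242 CPM in mouse and 0 in rat, and Prl8a2 was the member farthest toward rat. Symbols listed for only one of the species stayed out of these lists. In rat they held the hormones Prl8a5 (13135 CPM) and Prl3d4 (3637 CPM), and the cathepsin-like Ctsql1 (27990 CPM) and Ctsql2 (14399 CPM), which no list held. In mouse they held the cathepsins Cts6 (6272 CPM) and Cts3 (5437 CPM) and the hormones Prl8a6 (4012.5 CPM) and Prl8a8 (3241 CPM), which had been fixed for these lists. All of these are named after their values were seen. By its symbol Prl3d4 belongs with Prl3d1, so the 0 of Prl3d1 in rat does not stand for all Prl3d genes. Summed over the symbols that match a name pattern, in families also chosen after the data had been seen, placental cathepsins took 4.57% of the mouse and 7.755% of the rat counts. The prolactin family took 5.83% and 4.505%. Both families hold near-identical copies that differ in number between the species, so reads of 1 copy can be counted under another.

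Markers of the junctional zone, the layer next to the labyrinth, also lay toward mouse, with a median of -1.29 at the 0.070 percentile and 5 of 14 at least 4-fold higher in mouse against 1 in rat. Tpbpa, its most abundant marker, stood at 19380 CPM in mouse and 9925 CPM in rat, 1.95-fold higher in mouse. Prl6a1 was 83.5-fold higher in rat, and Aldh1a3 was listed at 21.8 CPM in mouse and 0 in rat. The list did not stand apart against unmatched random lists (3.12 percentile) or by its mean (4.44 percentile).

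Yolk sac endoderm markers were higher in rat, with 10 of 14 at least 4-fold higher there and 1 in mouse, and a median log2 ratio of 2.64 at the 100 percentile of the random lists. Afp (alpha-fetoprotein) stood at 1073 CPM in mouse and 4122 CPM in rat, 3.84-fold higher (3.76 to 3.92). Hnf4a, a regulator of endoderm genes, was listed at 17.0 CPM in rat and 0 in mouse. The apolipoprotein genes Apoa1 (4.40-fold) and Apob (6.13-fold), named after their values were seen, were higher in rat. Alb was the exception, 5.95-fold higher in mouse at 8.66 CPM.

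Decidua markers did not stand apart (median 0.36, 73.8 percentile), with Prl8a2 448-fold higher in rat and Wnt4 31.5-fold higher in mouse; 1 of 11 was at least 4-fold higher in rat and 2 in mouse. Fetal endothelial markers had a median of -0.37 at the 6.09 percentile, with 3 of 16 at least 4-fold higher in mouse and none in rat. Plvap, the most abundant, was 1.97-fold higher in rat, and Icam2 was listed at 11.4 CPM in mouse and 0 in rat. Pericyte and stromal markers had a median of -0.375 at the 6.24 percentile, with 5 of 15 at least 4-fold higher in mouse and 1 in rat. Postn was 33.0-fold higher in mouse, Col6a1 7.01-fold higher in rat, and Col3a1 stood at 456 and 450 CPM. Erythroid markers had a median of -0.15 at the 40.7 percentile (3 of 12 higher by 4-fold in each direction). Hba-a1 was 1.81-fold higher in rat, Epb42 was listed at 3.59 CPM in rat and 0 in mouse, and Slc4a1 at 16.2 CPM in mouse and 0 in rat. Leukocyte markers had a median of -0.50 at the 19.8 percentile (2 of 16 in each direction); Csf1r was 2.02-fold higher in mouse, Prf1 was listed at 1.75 CPM in rat and 0 in mouse, and Adgre1 at 3.60 CPM in mouse and 0 in rat.

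**Figure D4:**
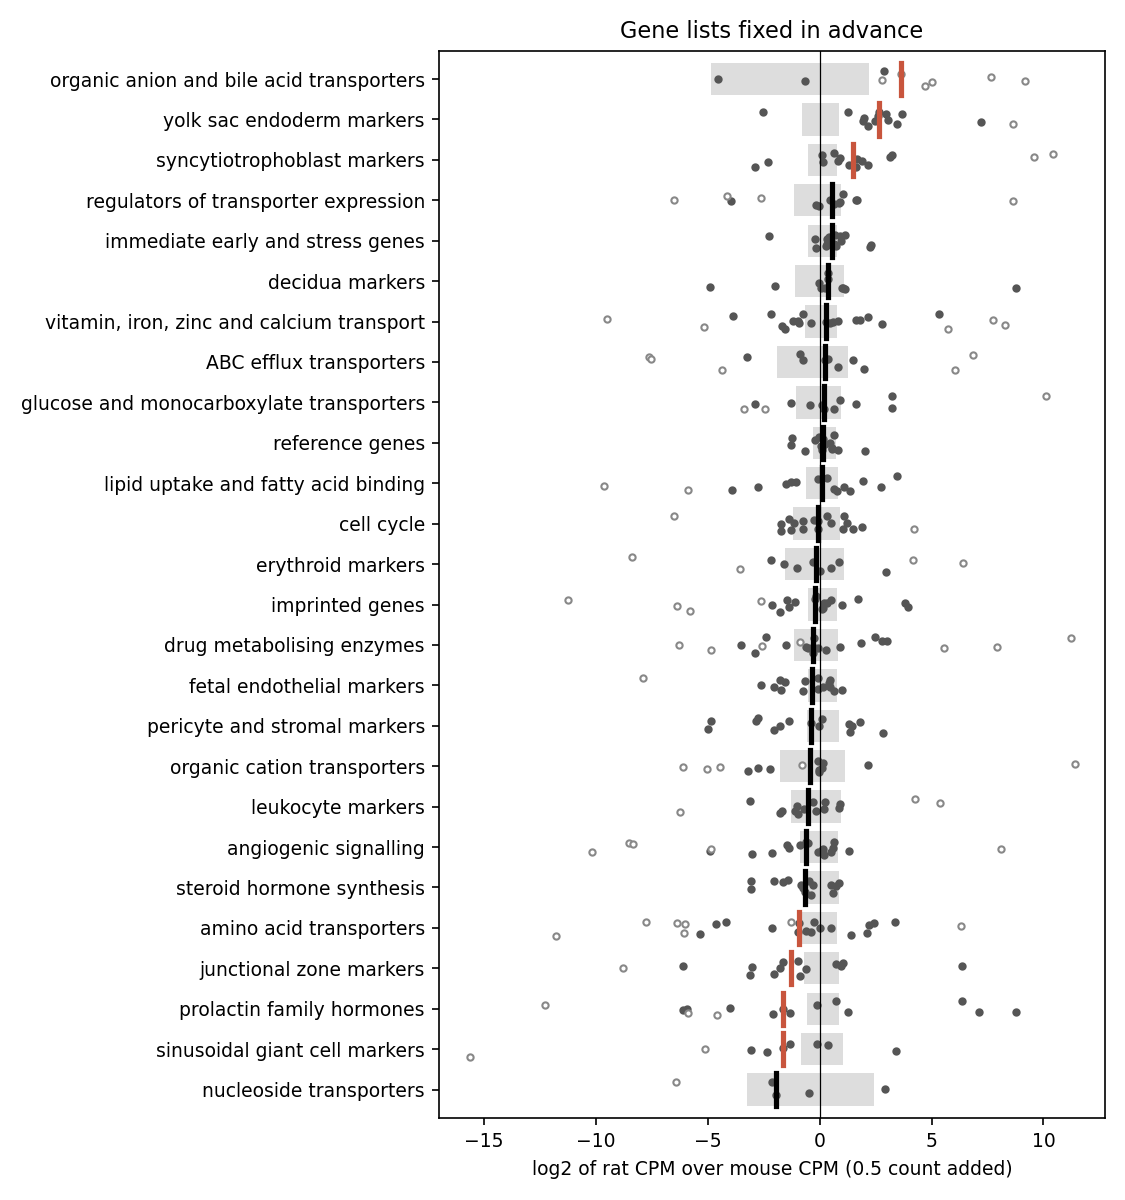
Log2 ratio of rat to mouse CPM (0.5 count added) for the measured members of 26 gene lists; open points are genes under 10 counts in a library, vertical bars are list medians (red where the list stands apart), and grey boxes span the central 95% of matched random lists. Yolk sac endoderm, syncytiotrophoblast and organic anion transporter medians lie to the right of their boxes, and amino acid transporter, junctional zone, prolactin family and sinusoidal giant cell medians to the left.

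Genes of hormone and drug metabolism did not stand apart as lists. In steroid hormone synthesis 3 of 15 genes were at least 4-fold higher in mouse and none in rat, with a median of -0.64 at the 3.90 percentile. Hsd11b1, which regenerates active glucocorticoid, was 8.51-fold higher in mouse (7.57 to 9.63), Hsd17b2 1.70-fold higher in mouse, and Cyp11a1, the first enzyme of steroid synthesis, 1.82-fold higher in rat. Among 23 drug metabolising enzymes, 6 were at least 4-fold higher in each direction, with a median of -0.31 at the 29.4 percentile. Comt, which methylates catechols, was 6.93-fold higher in rat, Xdh was listed at 102 CPM in rat and 0 in mouse, and Cyp1b1 at 3.77 CPM in mouse and 0 in rat.

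Regulators of transporter expression had a median of 0.55 at the 86.9 percentile, with 1 of 14 at least 4-fold higher in rat (Hnf4a) and 4 in mouse, of which Nr1h3 was listed at 4.45 CPM in mouse and 0 in rat. Cebpb, the most abundant, was 1.38-fold higher in rat. Angiogenic genes had a median of -0.63 at the 6.06 percentile, with 7 of 21 at least 4-fold higher in mouse and 1 in rat. Flt1, a receptor and decoy for VEGF, was 8.12-fold higher in mouse (7.78 to 8.47), Nrp1 was listed at 55.5 CPM in mouse and 0 in rat, and Dll4 at 11.6 CPM in rat and 0 in mouse. Imprinted genes had a median of -0.20 at the 13.9 percentile, with 2 of 20 at least 4-fold higher in rat and 5 in mouse. Peg10 stood at 7665 and 6532 CPM, Phlda2 was 15.3-fold higher in rat, and Sfmbt2 was listed at 117 CPM in mouse and 0 in rat.

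Cell cycle genes were close to equal as a list (median -0.07, 52.8 percentile), with 1 of 19 at least 4-fold higher in each direction. Pcna stood at 63.9 and 61.4 CPM, Mcm3 at 0.579 CPM in mouse and 11.6 CPM in rat, and Cenpf was listed at 4.37 CPM in mouse and 0 in rat. Reference genes had a median of 0.12 at the 37.8 percentile, and 15 of 16 were within 4-fold. The exception was Hprt1, 4.04-fold higher in rat; Eef1a1 was 1.58-fold higher in rat and Tbp 2.45-fold higher in mouse. Immediate early and stress genes had a median of 0.55 at the 89.35 percentile, with 2 of 16 at least 4-fold higher in rat and 1 in mouse. Hsp90aa1 was 1.60-fold and Gadd45a 4.84-fold higher in rat, and Hspa1b 4.83-fold higher in mouse.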

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

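Symbols with a value for only one of the species stayed out of every ratio and are a signal outside the comparisons. They took 11.07% of the mouse counts and 10.97% of the rat counts. In mouse the most abundant were Psg21 (12330 CPM) and Psg23 (11704 CPM) of the pregnancy-specific glycoprotein family and Tpbpb (10189 CPM). In rat they were the cathepsin-like Ctsql1 (27990 CPM), the globin Hbb (15052 CPM), Ctsql2 (14399 CPM) and the prolactin family hormone Prl8a5 (13135 CPM). A symbol listed for one species can reflect naming as well as gene content, as for beta-globins, where Hbb is listed for rat alone and Hbb-bt for mouse alone. The tests of too few reads, of widely used gene families, of curated records alone, of genes with 1 curated record and of left-out transcripts in the parts of the yolk sac list were chosen only after the result was seen.

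Widely used genes under 10 counts in 1 library form the first pattern. The tables argue against too few reads: of 217 genes of ribosome, proteasome, translation initiation, chaperonin and respiratory chain families, taken at any count, 5 were under 10 counts in 1 library alone, and equal expression with counting error gave a mean of 0.466 and at most 2 in 10000 draws. Of the 211 with at least 100 counts in a library, 4 (Rps14, Rpl11, Cox7a1 and Rps27) were under 10 in the other, which is 1.9% (95% interval 0.519% to 4.78%) and alone does not decide against a species difference in expression. Among genes with at least 500 rat counts, those with 2 or more mouse RefSeq mRNA records were 3.62 times as often under 10 counts in mouse as those with 1 (1.87 to 6.99). That result goes with a symbol's value covering only some of its transcripts. Among genes with at least 500 mouse counts, the ratio for under 10 counts in rat was 3.89 (2.62 to 5.77). It too was taken over mouse records. The number of rat transcripts per gene was not at hand, so the rat ratio cannot tell whether rat transcripts were left out. Counting curated records alone, the mouse ratio was 0.649 (0.411 to 1.03) and the rat ratio 1.99 (1.54 to 2.56), so the dependence in mouse rests on predicted records. Of the 4 genes named, Rps14, Rps27 and Cox7a1 have 1 record each and Rpl11 has 2.

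Slc47a1 at 0 in mouse is the second pattern. The rat level predicts 1338 mouse counts, so too few reads cannot account for the 0. Slc47a1 has 5 mouse RefSeq mRNA records, 1 curated and 4 predicted, and of 158 other genes with 5 records and 500 to 2500 rat counts 7 were under 10 counts in mouse, which is 4.43% (1.80% to 8.92%). Among 209 other genes with 1 curated and at least 3 predicted records the share was 11.5% (7.498% to 16.6%). A species difference in expression, which the design names, and a left-out transcript cannot be told apart for this gene from the table. Such shares count genes that are low for either reason, and the mouse value has no second measurement. The interval of the first share also spans the 5% set beforehand as the level for left-out transcripts, so that prediction was not decided. The species difference stays open and untested.

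Yolk sac endoderm markers higher in rat are the third pattern. The 7 members with 1 mRNA record lay at the 99.94 percentile of random lists of such genes (median 2.14). The direction toward rat therefore does not rest on members with several records alone. That percentile cannot decide on left-out transcripts for these 7 members, since 1 record in a mouse reference of another build does not exclude them. Rps27, with 1 record, was itself listed at 0 in mouse. The 7 members with several records had a median of 3.45. The difference was 1.31, where the central 95% of the 3432 splits of the 14 end at 1.06. Left-out transcripts stay open for the size of their ratios as well. More yolk sac endoderm RNA in the rat library is a candidate explanation, and a second list of 22 endoderm genes, with no gene in the first, lay at the 99.27 percentile with a median log2 ratio of 1.08 over 21 measured genes (most abundant, Slc13a4 at 334 CPM in mouse and 706 CPM in rat). That list was split, with 6 genes at least 4-fold higher in rat (Slc2a2, Vil1, Tmprss2, Apom, F2 and Cpn1) and 6 at least 4-fold higher in mouse (Apoa2, Spink1, Kng1, Pdzk1, Cldn2 and Gata4), which admixture alone would not give; of the measured genes, those but Apoa2, Spink1 and Kng1 had at least 10 counts in both libraries. Of the 14 measured genes of the first list 13 had at least 10 counts in both libraries, and higher expression within the rat labyrinth, the species and the gestational day stay open as untested.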

How the results depend on the processing

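No paired analysis was possible because each species had 1 library, and for the same reason no library could be left out; division by transcript length was not run. Of 418 values under alternatives, 394 stayed on their side and 13 moved. Moved means that a count changed by over 1.5 times, or that the Slc47a1 level or r went beyond its 95% interval. The interval of r takes genes as independent, which they are not, so for r the label is a convention only. A further 10 values, of 5 lists, no longer stood apart, and 1 list newly did, with the opposite sign. Many of the values that stayed could not have moved. A change of scaling shifts every log2 ratio alike and so leaves list percentiles nearly fixed. Filters, and thinning of the mouse counts, leave the rat Slc47a1 level as it was. No list that stood apart changed the sign of its median or mean where a value was obtained, while among the 19 others 10 values of 8 lists did. Organic anion transporters had no value with at least 10 counts in both libraries, since fewer than 4 members remained. Those were Slco2a1 and Slco4a1 in opposite directions, with Slco3a1 (log2 ratio -0.65, toward mouse) between them. Their median with no filter, 0.178, is the value of a gene at 0 in both libraries, so its sign says nothing. The Slc47a1 level in rat, 114.8 CPM, was 159 CPM with the total taken without the 50 most abundant genes and 126 CPM without globins and the prolactin family, by construction of the smaller total; mouse stayed at 0. With at least 10 counts in both libraries 862 genes were at least 4-fold higher in rat and 918 in mouse, in place of 1864 and 2637, and with the added restriction to genes with 1 mouse mRNA record 367 and 521 of 3333; both settings test fewer genes. At a 2-fold threshold 3230 genes were higher in rat and 3791 in mouse. Pearson's r of 0.439 was 0.420 without the 50 most abundant genes in the total, 0.737 with no filter, 0.698 with at least 10 counts in both, 0.575 with a pseudocount of 5 and 0.648 for genes with 1 mRNA record. Of 7 lists that stood apart, 4 did so against unmatched random lists, where amino acid transporters lay at 3.28, sinusoidal giant cell markers at 4.32 and junctional zone markers at 3.12. By the mean in place of the median, amino acid transporters lay at 3.03 and junctional zone markers at 4.44. Amino acid transporters lay at 9.23 with no filter, 7.45 with 10 counts in both and 3.35 with a pseudocount of 5, and organic anion transporters at 57.1 with no filter. For genes with 1 mRNA record, syncytiotrophoblast markers lay at 66.7 (4 genes) and lipid uptake genes at 1.21 (6 genes, median -1.28 in place of 0.12). Where no construction is named, the cause was not tested. Genes under 10 counts, and precision that 1 library per species cannot give, limit the rest.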

Other observations

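Summed over the symbols that match a name pattern, whether or not the other species has the same symbol, the large placental gene families took different shares of the libraries. A member under another name was not counted. The families were chosen after the data had been seen, and the intervals cover counting error only. Symbols beginning with Psg or Ceacam (pregnancy-specific glycoprotein and Ceacam genes) made up 6.99% of the mouse counts (95% binomial interval 6.98% to 7.01%) over 29 symbols. In rat they made up 0.927% of the counts (0.921% to 0.933%) over 13 symbols. Other names were left out, among them Cgm4 (1261 CPM, listed for rat alone), so naming can lower the rat share. Placental cathepsins made up 4.57% in mouse and 7.755% in rat, led by Ctsj in mouse (1.94%) and Ctsql1 in rat (2.80%). The prolactin family made up 5.83% in mouse and 4.505% in rat, led by Prl3b1 (2.68%) and Prl8a5 (1.31%). Globins, which come with blood, made up 3.27% in mouse and 4.58% in rat. Tpbpa and Tpbpb together made up 2.96% of the mouse counts, and Tpbpa, the only one of the pair listed for rat, 0.993% of the rat counts.

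Single members differed from their family's sum in size and direction; those given here were also chosen after their values were seen. Ctsj was 1.09-fold and Ctsq 8.28-fold higher in mouse, while the cathepsin sum was higher in rat. Prl2b1 was 60.2-fold and Prl3a1 68.9-fold higher in mouse, Prl4a1 was 140-fold higher in rat, and Prl7c1 stood at 8.76 CPM in mouse and 8.15 CPM in rat, while the family sums were 5.83% and 4.505%.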
